A study of Drosophila melanogaster with 3 samples.

How the data were processed

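Array comparative genomic hybridisation was done on 3 two-colour Agilent arrays, 1 for each of the groups X_euchromatin_lost, 2L_euchromatin_lost and 3L_euchromatin_lost. Per the labels, Cy5 marked DNA of embryos from a translocation cross, collected at 3.5 to 8 hours, and Cy3 marked DNA of Oregon R embryos, collected at 0 to 8 hours, on every array. Dyes were not swapped, so a dye effect that acts on all probes of a kind stays in the ratios. DNA was extracted with proteinase K and phenol/chloroform and labelled by random priming with the BioPrime kit, per the labels' protocols. Each array sat on a slide of its own, per the file headers, so slide and group cannot be told apart.

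The scanner files hold the intensity of each spot in both channels, extracted with Agilent Feature Extraction 9.5.3.1, per the file headers. The processed signals in these files were background-subtracted (method code 7 of the settings block), corrected for spatial and multiplicative trends and normalised between dyes with 1 linear factor per channel, per the file headers. The mean spot signals and local background medians are uncorrected. Probes are placed on build dm3, release 5, per the file headers. The authors also deposited a value table with 1 log2 value per probe and array. The submitters' processing notes name limma, with no version or step, and neither its centring nor its background correction is given in the sources used here. Set against the scanner values across probes, its columns correlated with the log2 ratio of mean signals at r = 0.992, 0.986 and 0.988 (slopes 0.926, 0.865 and 0.952) and with that of processed signals at 0.948, 0.949 and 0.953. It is therefore a log2 ratio of Cy5 over Cy3. Its column medians were 0.02, -0.05 and -0.21 on the X, 2L and 3L array.

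Every array had 103747 spots with 83472 probe names of 60 bases, of which 23401 have a position in the files and 60071 have none. Spots marked as non-uniform or population outliers in either channel were left out (795, 851 and 696), as were spots whose Cy3 signal was not well above background (2141, 2111 and 1746). No filter was set on Cy5, since a lost sequence has low signal there. The log2 ratio of the processed Cy5 and Cy3 signals was averaged over the spots of a probe and centred on the array median, which before centring was -0.20, -0.12 and -0.14. No loess or quantile step was used. There were 81334, 81337 and 81658 usable probes. Precision is limited by the number of arrays, which is 1 per group. In lost regions the median Cy5 signal was 36.0, 16.2 and 62.3, or 16.2, 7.72 and 26.6 times that of the 300 negative control spots, and 0 spots were saturated.

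Unless said otherwise, the following choices were made before the data were examined. A single change point was fitted by least squares to the probes of the named arm in order of position, with at least 20 probes on each side, and its interval was taken from 1000 resamples of the probes, which covers probe noise only. On X these resamples formed separate groups, so the interval given, a choice made after the data were seen, is that of resamples within the last 5 Mb. The midpoint of both fitted levels, which are means, separated lost from retained probes, and shares on scaffolds, which had no part in the fit, carry 95% Wilson intervals that cover probe sampling only. The same fit was run on all arms with 200 or more probes, and a step was reported where the levels differed by 0.3 or more with 50 or more probes on each side. Levels relative to other arms are 2 to the power of a difference of medians. The arms used were 2L, 2R, 3L and 3R on the X array, X, 3L and 3R on the 2L array and X on the 3L array.

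Genes were named from lists fixed beforehand, namely distal and proximal landmarks of X, 2L and 3L, the histone repeat, 2R and 3R landmarks, heterochromatic genes of 2R, 3L and 3R, chromosome 4 genes, Y genes and X repeats with their Y partners. The rule named each member with 3 or more usable probes, and the 5 genes of that size nearest to each side of the change point. Of 138 listed genes, 120 were found by the name in the files and 14 by another name or accession in a RefSeq table of release 6, whose coordinates were not used. The 4 others had no probe, and ri was left out because the files use it as another name of kni. On each array 45 genes had 3 or more probes, and a gene's value is the median over them. A list's median was placed among 10000 random lists of the same size, matched on the Oregon R signal in 10 classes, as a description of these arrays.

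With 1 array per group no test between groups could be run and no p-value was computed. The change point fit was tested on simulated arms with the noise of an arm not lost, 3R for the X and 2L array and X for the 3L array. That noise had a MAD of 0.28, 0.30 and 0.43, below that of the lost probes (0.95, 1.21 and 0.65). No kept tip was simulated. On these simulated arms the fit came within 3 probes of the true point in 100%, 100% and 99.0% of 200 draws for the X, 2L and 3L array. It called 0, 0 and 1 step in 200 draws of an arm without one. The accuracy on the real, noisier arms was not measured by this. Alternatives fixed beforehand were normexp background correction with an offset of 50 on the mean signals, centring on arms that neither label nor translocation names, other filters on dim probes, the authors' value table, subtraction of the mean of the other arrays, probes found once on the array, loess, and other thresholds. Where only probes above the median Oregon R signal were used, ratios were centred anew on the median of those probes. Added after the data were seen were probes with 30 to 40% G and C, steps with 20 probes on each side, unplaced probes taken singly and genes with 1 or more probes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.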

Results

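Genomic DNA of Drosophila melanogaster embryos that lacked most of 1 chromosome arm was compared with DNA of Oregon R wild-type embryos by array comparative genomic hybridisation. In this assay the DNA of both sources is labelled with different dyes and hybridised to the same probes, and the ratio of the dyes follows the copy number of the sequence under each probe. Embryos without the euchromatin of X, 2L or 3L came from crosses of males carrying a translocation, T(1;Y)B91, T(Y;2)R146 or T(2;3)H31, with females whose matching chromosomes were joined to each other (attached-X, C(2)EN or C(3)EN). Each translocation breaks X, 2L or 3L near the border between euchromatin, the gene-rich part of an arm, and the repeat-rich heterochromatin around the centromere. The question was which sequences lie on the heterochromatic side of that border. There were 3 arrays, 1 for each arm (the X, 2L and 3L array), so no value below has a replicate check and no p-value is given. Usable probes numbered 81334, 81337 and 81658 on the X, 2L and 3L array. Ratios are log2(Cy5 of the translocation embryos / Cy3 of Oregon R), centred on the median of each array, and each spread is the median absolute deviation (MAD) over probes or a range over the probes of a gene. Positions are those of the files, on genome build dm3 (release 5).

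On the X array, the euchromatin of X was depleted to 0.136 of the level of the large autosomal arms, and genes next to the centromere were kept. The Notch receptor gene N had a median log2 ratio of -2.54 (3 probes, range -3.31 to -1.38), the bristle gene sn, which encodes the actin-bundling protein fascin, -2.99 (3 probes, -3.56 to -2.05), and the eye pigment granule gene car -2.04 (3 probes, -3.74 to 0.08). The ventral furrow gene fog, at 22228014 to 22255678 of X in bands 20D2-20E1, lay at -0.87 (3 probes, -0.90 to -0.63), and CG41106, further proximal, at -0.58 (3 probes, -0.65 to -0.32). The change between both levels was fitted between CG41476, whose last probe ended at 22164035, and the next probe at 22181094. The 3673 probes distal to this point had a median of -2.97 (MAD 0.95), and the 35 probes proximal to it a median of -0.60 (MAD 0.38). Under the alternative settings the distal median ran from -3.29 to -2.22. The same distal probes had medians of 0.31 on the 2L array and 0.07 on the 3L array.

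All 4 of the distal X landmark genes with 3 or more probes lay below the midpoint of both levels (-1.53). These were N, sn, car and the bristle gene f (-2.18), and their median of -2.36 stood at percentile 5.58 of random gene lists matched on Oregon R signal. The pool of 1313 genes for these lists held the other genes of the lost arm too. Over all 13 distal list members with 1 or more probes, a count added after the data were seen, 10 lay below the midpoint. Those above it were y, ac and w, and w (-1.05, 2 probes from -2.15 to 0.05) lies at 2685266 to 2686905, inside the lost part. Of the 3 measured proximal X genes, DIP1, a gene for a double-stranded RNA-binding protein in bands 20A4-20A5, had a median of -1.78 (range -2.56 to -0.52) and lay below the midpoint. The gap junction gene shakB, with a median of -0.67 and probes from -3.15 to 0.21, and fog lay above it, for a list median of -0.87. Of these, shakB (20642540 to 20697070) and DIP1 lie distal to the fitted change point. Over all 14 list members with 1 or more probes, a count added after the data were seen, the median was -1.50 and 7 lay below the midpoint, among them run (-3.20) and fliI (-4.25). The nearest distal genes were Sep1 (-2.91), waw (-2.48), DIP1, CG14617 (-3.22) and l(1)G0196. In l(1)G0196, at 21893779 to 21909287, the median of -0.90 joined 5 probes that ran from -2.99 to -0.20. Only 2 genes with 3 or more probes, fog and CG41106, lay on the proximal side.

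Of the 20 probes on the XHet scaffold, which had no part in the fit, 17 lay at or above the midpoint on the X array (85.0%, 95% Wilson interval 64.0 to 94.8). All 35 proximal probes of the arm did so too, but on each array the share in the proximal part is partly set by the fit, which placed the change point and the midpoint on the same probes. The XHet median was -0.60 (MAD 0.48), against 0.54 on the 2L array and 0.02 on the 3L array. Among probes above the median Oregon R signal, centred anew on their own median, the XHet value on the 2L array was 0.039. A second group of kept probes lay at the other end of the arm, a result singled out after its values were seen. The 30 most distal probes, from 20920 to 264859, had a median of -0.80 (MAD 0.16), and all 30 lay above the midpoint. The last of them covered the pigment gene y (-0.75) and the proneural gene ac (-0.95), each with 1 probe. The next probe, in the neighbouring proneural gene sc at 291298, had a ratio of -2.98, and the remaining 3643 lost probes a median of -2.98 (MAD 0.94).

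**Figure D1:**
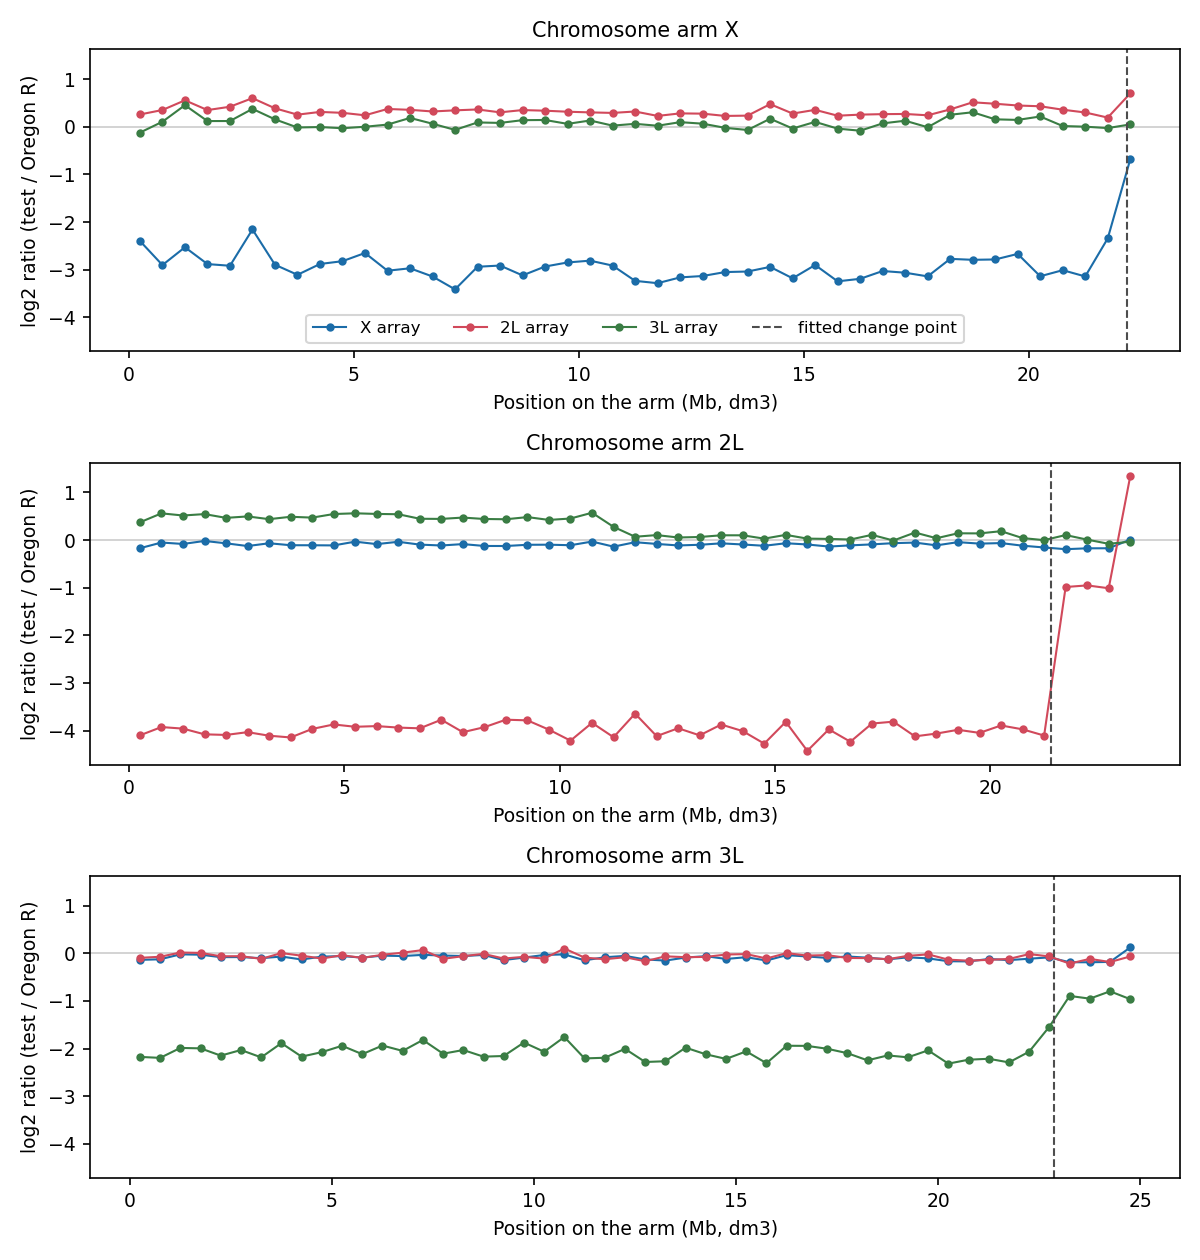
Median log2 ratio in bins of 500 kb (points) along X, 2L and 3L (dm3, Mb) on the 3 arrays, with the fitted change point as a dashed line. Each arm is low on its own array up to the change point, with probe medians of -2.97, -4.00 and -2.10, and the last bin of 2L holds 1 probe. The tip of X is an exception, with a median of -0.80 up to 264859, which the first bin does not show.

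On the X array the large autosomal arms and chromosome 4 lay close to the array median. The medians of 2L, 2R, 3L and 3R ran from -0.10 to -0.09, and chromosome 4 had a median of -0.19. The Y scaffold YHet had 0.73 (MAD 0.30, 17 probes), which was 0.051 among probes above the median Oregon R signal, centred anew on their own median. The coiled-coil protein gene CCY of the Y, with 4 probes from 0.71 to 0.81, had a median of 0.77, and so did WDY, also on the Y. Stellate (Ste), a repeated X gene that is silenced by the Y locus Su(Ste), had a median of -2.32 (3 probes, -2.36 to -1.34), whereas Su(Ste) had 1.27 (4 probes, 1.10 to 1.65). The median over this pair was -0.53. Without the histone genes, the 9 lists of genes on 2L, 2R, 3L, 3R and 4 had medians between -0.32 and -0.04, and none of their 29 measured genes lay below the midpoint. In 77 of 1000 resamples of the probes (7.70%) the single change point fell outside the last 5 Mb of X, and the 95% interval over all resamples began at 291298, at the step between ac and sc. Among the others 95% of positions lay between 21904672 and 22228408. When only probes above the median Oregon R signal were used, the change point moved to 21244034, and 73.9% of the probes proximal to it were retained.

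On the 2L array, 2L was depleted to 0.060 of the level of X, 3L and 3R, while 2R and proximal 2L both lay at 0.49 of it. The arms behind this level were not equal, as X lay at 1.20 of it and 3L and 3R at 0.92. The morphogen gene wg had a median log2 ratio of -5.30 (3 probes, range -5.52 to -1.58), the tumour suppressor l(2)gl at the tip of the arm -4.12 (4 probes, -4.69 to -3.81) and the alcohol dehydrogenase gene Adh -2.88 (3 probes, -5.07 to -2.54). On the other side of the break, the ribosomal protein gene RpL5 lay at -1.11 (7 probes, -1.17 to -0.59) and the eye colour gene lt, which sits in heterochromatin, at -1.06 (4 probes, -1.17 to -0.98). The change was fitted between 21390717, just beyond nrv3 in band 39D2, and 21405275, and 95% of resamples placed it between 21319391 and 21547180. The 3860 distal probes had a median of -4.00 (MAD 1.21), and the 161 proximal ones -0.97 (MAD 0.38). The distal probes had medians of -0.10 on the X array and 0.37 on the 3L array.

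All 4 measured landmark genes of distal 2L, which included the POU-domain gene nub (-3.65, 5 probes from -5.69 to 0.94), lay below the midpoint of -2.17. Their median was -3.88, at percentile 0.11 of matched random lists. Over all 14 list members with 1 or more probes, 12 lay below the midpoint. The nearest distal genes, CG9339 (-3.86), Nhe2 (-4.20), the nuclear receptor gene Hr39 (-3.49), the taste receptor gene Gr39a (-3.79) and the sodium pump gene nrv3 (-4.49, at 21382254 to 21390339), were all below it. On the proximal side, CG3305 in band 39E2 (-1.09), CG31619 (-1.05) and CG6448 (-1.09) lay close to the kept level. Df31, which encodes a chromatin decondensation factor, had -0.56, and step, with probes from -0.93 to 0.63, had 0.38. The list of proximal and heterochromatic 2L genes had 2 measured members, RpL5 and lt, none below the midpoint, and a median of -1.08.

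The tandem histone genes, which start at band 39D3 next to the fitted change point, had ratios between both levels, on a side of the midpoint that depended on the setting. His1 had -1.64 (5 probes, -1.84 to -1.51), His2A -1.89, His2B -1.85, His3 -1.29 and His4 -1.50. The list median of -1.64 stood at percentile 0.01, and none of the 5 genes lay below the midpoint. After loess normalisation all 5 lay below the midpoint of that setting (-1.82), with a list median of -2.62 against -3.34 for distal 2L. In the authors' value table all 5 did so too (midpoint -1.49), with -2.05 against -2.66, and after normexp correction 2 of the 5. On the X array the same list had a median of 0.26. The files place most of these probes on Uextra and not on 2L.

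**Figure D2:**
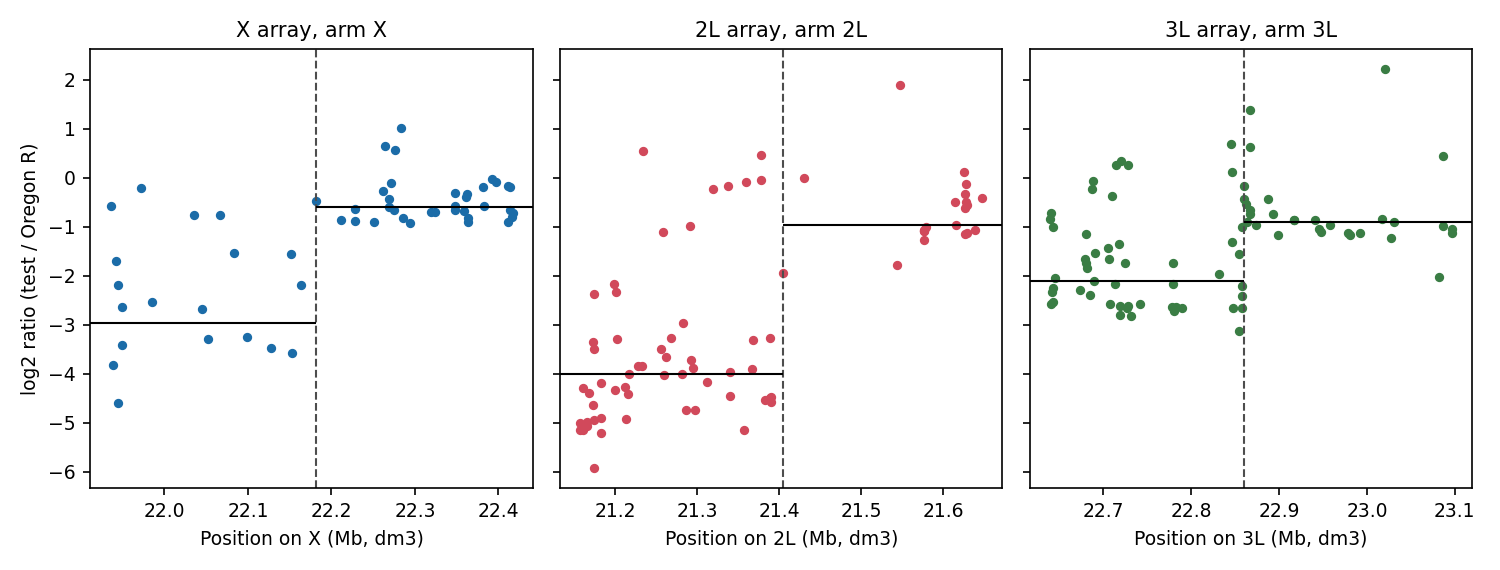
Log2 ratio of single probes (points) within 250 kb of the change point (dashed line) of X, 2L and 3L, each on its own array, against position (Mb, dm3). Solid lines are the medians of all distal and all proximal probes of the arm, -2.97 and -0.60 on X, -4.00 and -0.97 on 2L, and -2.10 and -0.90 on 3L.

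All 37 probes of 2LHet (100%, 90.6 to 100) and all 161 proximal probes of 2L lay at or above the midpoint on the 2L array. The median of 2LHet was -0.11 (MAD 0.51), but most of its probes were brighter than 95% of the arm probes. The 10 others had a median of -0.99. The whole of 2R had a median of -0.97 (MAD 0.37), equal to that of proximal 2L. After loess normalisation 2R had -0.58 and proximal 2L -0.66. The mitogen-activated protein kinase gene rl in 2R heterochromatin had -1.21 (6 probes, -1.87 to -1.07), Nipped-B, for the loader of cohesin, -1.13 and the transcription factor gene ap -1.11. The 2R heterochromatic list, with rl, Nipped-A (-1.05), Nipped-B, uex (-0.62) and p120ctn (-1.04), had a median of -1.05, and the 2R landmarks ap, sca (-0.73) and bw (-0.63) had -0.73. Neither list had a member below the midpoint.

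Further chromosomes differed from the array median on the 2L array. X had a median of 0.32 (MAD 0.36) and XHet 0.54 (MAD 0.47), whereas 3L and 3R each had -0.07 and chromosome 4 had -0.19. YHet had a median of 0.81 (MAD 0.58). Among probes above the median Oregon R signal, centred anew on their own median, X had 0.096, 3L -0.28, XHet 0.039 and YHet 0.16, so X stayed above 3L. Genes of the Y differed from each other. CCY had 0.81 and WDY -0.82, with probes from -5.34 to -0.26, for a list median of -0.01 that joins opposite values. Over all 11 Y genes with 1 or more probes the median was 0.94. Among Y genes with fewer probes, named after their values were seen, the dynein gene kl-5 had 1.76 (2 probes), ARY -2.39 and Ppr-Y -4.79 (1 probe each). Without Ste and Su(Ste), whose median was 0.76, the list medians of X, 3L, 3R and 4 genes ran from -0.20 to 0.55, and none of their 22 measured genes lay below the midpoint. The depth of the loss differed between sources of values. The distal 2L median was -2.73 from mean signals after normexp correction and -2.66 in the authors' value table. With a fixed level of -1 in place of the midpoint, 52.8% of proximal 2L probes counted as retained. That level lies next to the kept median of -0.97, so it splits the kept probes and does not measure a loss.

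**Figure D3:**
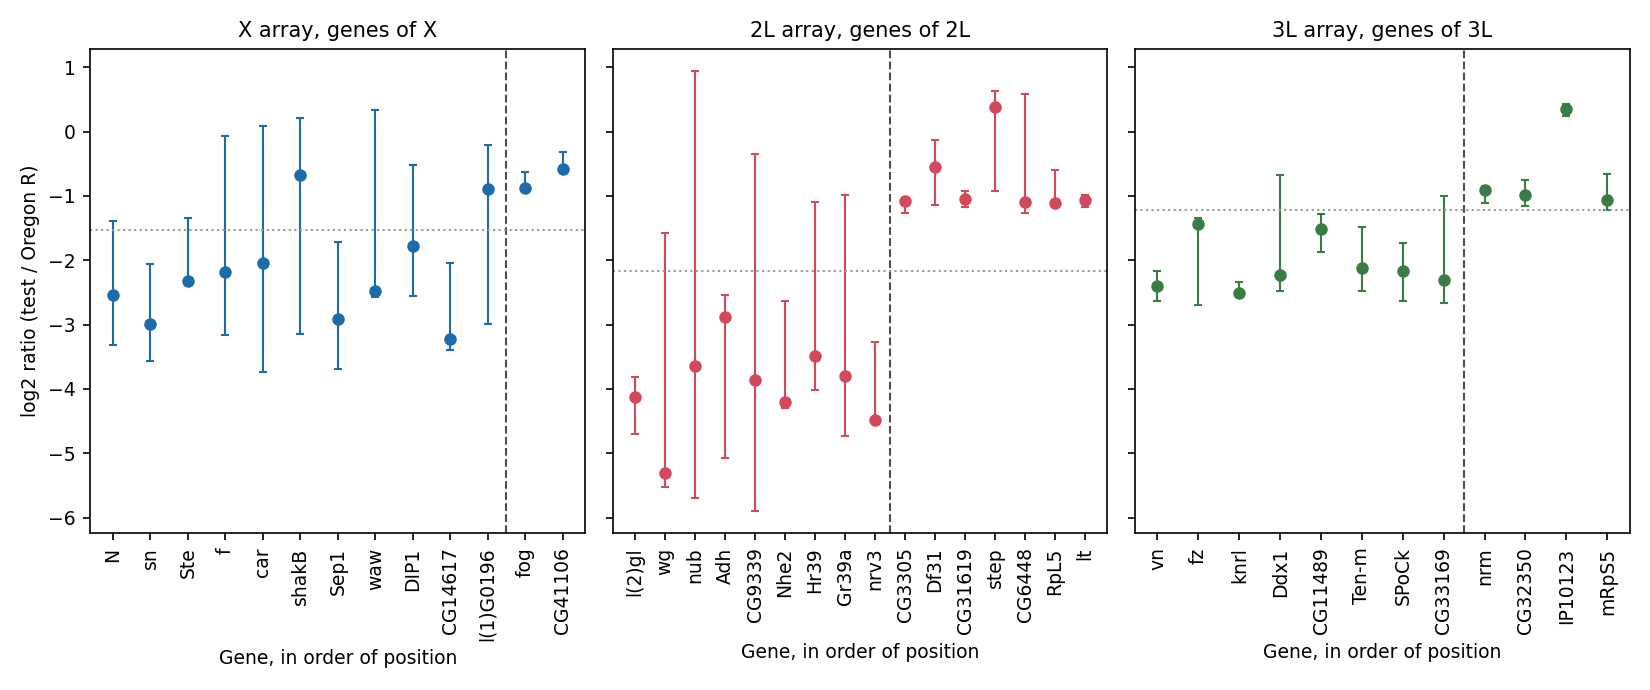
Median log2 ratio of genes with 3 or more probes on the arm each array lacks, in order of position. Bars are the range over the probes of a gene, the dashed line is the change point and the dotted line the midpoint of both levels (-1.53, -2.17 and -1.22). On the 2L array nrv3 lies at -4.49 and CG3305, on the other side of the change point, at -1.09.

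On the 3L array, 3L was depleted to 0.222 of the level of X, and proximal 3L, 3R and the 3LHet scaffold lay between 0.51 and 0.61 of it. The lost arms of the X and 2L array lay at 0.136 and 0.060, each relative to a different set of arms. The epidermal growth factor ligand gene vn had a median log2 ratio of -2.40 (5 probes, range -2.63 to -2.16), the gap-gene relative knrl -2.50 (3 probes, -2.57 to -2.33) and the Wnt receptor gene fz -1.43 (3 probes, -2.70 to -1.34). The cell adhesion gene nrm, in bands 80C2-80C4, lay at -0.91 (3 probes, -1.12 to -0.85), and the helicase gene Dbp80, on the 3LHet scaffold, also at -0.91 (3 probes, -0.92 to -0.45). The change was fitted between CG33169, whose last probe ended at 22858209, and CG33170, whose probe started at 22860552, both in band 80B1. Resampling placed it between 22845511 and 22863026. The 4304 distal probes had a median of -2.10 (MAD 0.65), and the 79 proximal ones -0.90 (MAD 0.34). Under the alternative settings the distal median ran from -2.29 to -1.60. The distal probes had medians of -0.10 on the X array and -0.07 on the 2L array.

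All 3 measured landmark genes of distal 3L lay below the midpoint of -1.22. Their median was -2.40, at percentile 0.23 of matched random lists. Over all 19 list members with 1 or more probes, 17 lay below the midpoint. The nearest distal genes were Ddx1 (-2.23), CG11489 (-1.52), the teneurin gene Ten-m (-2.12), the calcium pump gene SPoCk (-2.16) and CG33169 (-2.31). On the proximal side, CG32350 (-0.99) and the mitochondrial ribosomal protein gene mRpS5 (-1.06) lay close to nrm, and IP10123, at 23908427, had 0.36, which was -0.064 in the authors' value table. The 3L heterochromatic list, with nrm and Dbp80 as its measured members, had a median of -0.91. On 3LHet, 100 of 105 probes lay at or above the midpoint (95.2%, 89.3 to 97.9), as did 71 of the 79 proximal probes of 3L. The 3LHet median was -0.65 (MAD 0.57), and that of its 66 probes of ordinary brightness -0.96.

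The arm 3R lay below the array median on the 3L array, at -0.76 (MAD 0.40), and its best single split gave medians of -0.80 and -0.75. The homeotic genes Antp (-0.94, 4 probes from -1.12 to 0.55) and Abd-B (-0.31, 4 probes from -1.10 to 0.22, and 0.13 after loess normalisation) and the bristle and leg gene ss (-1.19, 3 probes from -1.24 to 1.16) gave a median of -0.94. The heterochromatic myosin gene Myo81F had -0.97 (6 probes, -1.20 to -0.80), and the 3RHet scaffold -0.56 (MAD 0.49).

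**Figure D4:**
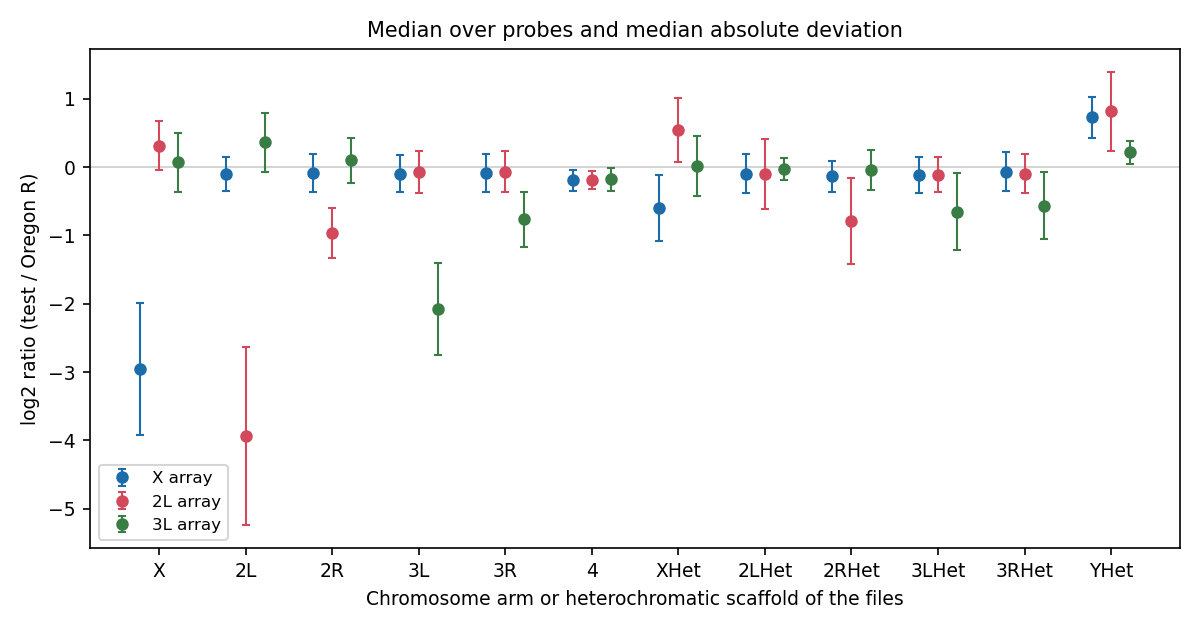
Median log2 ratio of the probes of each arm and heterochromatic scaffold on the 3 arrays, with bars for the median absolute deviation over probes. On the 2L array 2R lies at -0.97 and on the 3L array 3R at -0.76, while X lies at 0.32 on the 2L array and YHet at 0.73 and 0.81 on the X and 2L arrays.

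The scan for further steps found 1 on arms that the label does not name, on 2L of the 3L array. The translocation behind this array also has a breakpoint on chromosome 2, and whether the step marks it was not tested. The 2293 probes distal to the step had a median of 0.48 (MAD 0.31), and the 1753 probes from 11076487 on 0.07 (MAD 0.29). The fit placed the step inside the neuropeptide gene Ast-C in band 32D2, between probes at 0.47 and 0.18. No resample interval was taken for it, and its place differed between settings. It fell between 11069035 and 11071062 with loess. In the authors' value table and with 30 to 40% G and C it fell between 11090674 and 11090704. A break inside this gene is thus not shown. The tip gene l(2)gl, on the distal side, had 0.51 on this array (4 probes, 0.36 to 0.96), and RpL5, on the proximal side, had 0.01 (7 probes, -0.05 to 0.66). The histone genes had a list median of 0.67 there, which loess normalisation turned to -0.03. Ste, on X, had -1.40 and lay below the midpoint, and with Su(Ste) it had a median of -0.39. Without these and the histone genes, the list medians of X, 2L, 2R and 4 genes ran from -0.15 to 0.39, and none of their 27 measured genes lay below the midpoint. Chromosome 4 had a median of -0.18, 2R 0.10, YHet 0.22 and the Y genes CCY and WDY 0.01 and 0.37, with a list median of 0.19. The YHet value was -0.12 among probes above the median Oregon R signal and 0.86 after loess normalisation, and subtracting the mean of the other arrays gave -0.46. The list median of Y genes was 0.67 after loess normalisation and -0.23 after that subtraction, and 0.36 over all 11 genes with 1 or more probes. Over all 6 measured genes of chromosome 4, among them the transcription factor genes pan and sv and the synaptic gene unc-13, the list medians were -0.22, -0.20 and -0.15 on the X, 2L and 3L array.

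**Figure D5:**
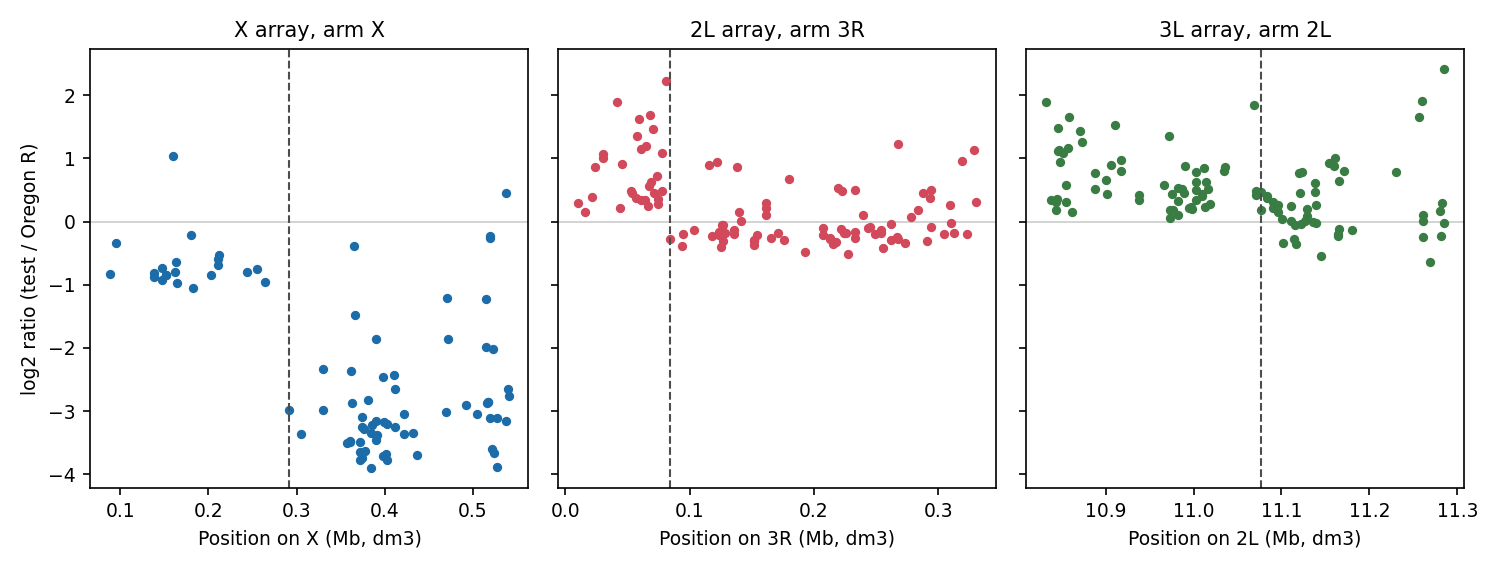
Log2 ratio of single probes (points) against position (Mb, dm3) around 3 further steps (dashed lines). They lie at the tip of X on the X array, at the proximal end of 3R on the 2L array and inside 2L on the 3L array. The probe medians on both sides of the lines are -0.80 and -2.98, 0.59 and -0.07, and 0.48 and 0.07.

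Most probes of the array had no position in the files. There were 60071 such probes under 58439 contig or sequence names, of which only 3 had 5 or more probes, and 0 of these 3 lay below the midpoint on 1 array alone. Taken probe by probe, a count added after the data were seen, 56766 unplaced probes were usable on all 3 arrays. Of these, 2624 (4.62%) lay below the midpoint on the X array alone, 3995 (7.04%) on the 2L array alone and 6211 (10.9%) on the 3L array alone. Kinds of probe names differed in these shares. Among 25597 probes named as contigs they were 7.21%, 12.9% and 20.8%, and among 13351 probes with names starting with nw they were 2.17%, 0.352% and 2.07%. In all, a further 41121 (72.4%) lay above it on every array. Another 2815 lay below it on 2 or 3 arrays, 2591 of them probes named as contigs, whereas only 4, 7 and 5 placed probes of X, 2L and 3L did so. Each array lacks a different arm, so the loss of 1 arm does not account for such probes. Placed probes give the yield of this count for their own kind only, since 80.7% of the probes of X, 79.9% of those of 2L and 78.5% of those of 3L fell below the midpoint on their own array alone. The yield among unplaced probes was not measured. Their base composition differed, with a median of 31.7% G and C for contig names and 43.3% for nw names, against 36.7% for the kind that was placed. The count also has false entries, as 4.14% of the probes of 3R fell below the midpoint on the 3L array alone. How many false entries it has among unplaced probes is not known. Ratios of lost probes differed with base composition. Lost X probes with 35 to 40% G and C had a median of -3.29 on the X array, and those with 55 to 60% had -0.79, so that the second kind can lie above the midpoint although their arm is lost. The mitochondrial genome, with 29 probes, had medians of -1.47, -0.32 and -0.86 on the X, 2L and 3L array. These were -2.44, -1.44 and -1.63 after loess normalisation, and the value table gave -0.70 on the 2L array. Subtracting the mean of the other arrays turned the 2L and 3L array to 0.81 and 0.066.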

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

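All tests in this part were chosen after the results were seen. Among the medians of arms and scaffolds, 3 pairs of arrays had opposite signs with at least 0.3 on each side, and none of these differences was tested, since each array stands alone. X lay at -2.96 on the X array and 0.32 on the 2L array (difference -3.27). The arm 2L lay at -3.94 on the 2L array and 0.36 on the 3L array (difference -4.30). The scaffold XHet lay at -0.60 on the X array and 0.54 on the 2L array (difference -1.14). Among probes above the median Oregon R signal none of the 3 pairs reached 0.3 on both sides, as X and XHet had 0.096 and 0.039 on the 2L array and 2L had 0.14 on the 3L array. That setting is centred anew on the median of its own probes, and 3L on the 2L array was lower in it too (-0.28 against -0.07). X thus still lay above 3L there, and values near 0 do not show that the difference between these arms was gone.

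X lay above 3L and 3R on the 2L array by 0.38. Base composition was argued against as the whole cause, since among probes with 30 to 40% G and C the difference was still 0.36 (95% of resamples 0.34 to 0.37). A candidate explanation is that every embryo of the 2L array had 2 copies of X, while the Oregon R embryos were an even mix of the sexes, which would put X at 1.33 of the level of 3L and 3R. The measured level was 1.28 (1.27 to 1.29), near 1.33 but with a resample interval that leaves it out. Whether the sexes were even in either pool was not measured.

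The lost arm was less deep on the 3L array (-2.10) than on the others. Compression of all its ratios was argued against, because the drop of 3R there was 0.87 of the drop of 2R on the 2L array (0.84 to 0.89), while for the lost arms this value was 0.54. A constant unspecific signal was argued against as the whole cause, because the brightest probes of lost 3L lay 0.22 above the dimmest (0.11 to 0.33; 0.61 for lost 2L), while a constant that lifts lost 2L to the level of lost 3L would give -0.94. Some of the embryos may have carried 3L, and the share this needs was 0.15 from 3R, 0.21 from 3L and 0.33 from the step on 2L. These shares disagree by more than their resample intervals, so this stays open, as does a difference between the crosses, which was not tested.

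Mitochondrial probes lay lower on the X array (-1.47) than on the 2L array (-0.32). Saturation was argued against, because 0 mitochondrial spots were saturated. The mitochondrial medians differed by -1.15 and those of 34 equally bright probes of 3L and 3R by -0.49 (95% of resamples -0.52 to -0.44). This argues against a different dye response at high brightness as the whole cause, and leaves it open for a part. No biological explanation was tested.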

How the results depend on the processing

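The levels, positions, shares, steps and unplaced counts of each array were recomputed under the alternatives below, with its gene lists and their members of 3 or more probes. Other values, among them single genes set beside these from another array, genes with fewer probes, the tip of X, the V-named probes and the tests of explanations were not. Of the alternatives, the limits to 30 to 40% G and C, to 20 probes beside a step, to single unplaced probes and to genes with 1 or more probes were chosen after seeing the data. A median of a region counted as moved when it shifted by more than the MAD over the probes of that region, a gene or list median when it shifted by more than the MAD over the lost or the kept probes of the arm that array lacks, a share when it left its 95% Wilson interval, a position when it left its resample interval and a count when it changed by more than 1.5 times. By this measure 25 of 27 values of the lost arms, 32 of 33 positions, 359 of 405 medians of other regions and 140 of 156 list medians stayed. So did 49 of 66 shares, 28 of 33 step counts, 20 of 24 unplaced counts and 492 of 548 gene values, with 4 genes reversed. Lost arms ran from -3.29 to -2.22 on the X array, -4.28 to -2.66 on the 2L array and -2.29 to -1.60 on the 3L array, without a change of sign, and centring on the unnamed arms, no filter on dim probes and sequences found once moved none of the results compared here, genes included. The last settings named are a weak check, since they changed values little: lost X on the X array went from -2.97 to -2.88, -2.99 and -2.98. With normexp, lost 2L had -2.73 on the 2L array. With the authors' value table it had -2.66, 3LHet of the 3L array was retained at 80.0%, and the lists of distal 2L and histone genes had -2.66 and -2.05 on the 2L array. M had -1.78 on the X array and -0.70 on the 2L array, 4 had -0.049 on the 2L array and 2LHet -0.23 on the 3L array, and the gene IP10123 was reversed on the 3L array (-0.064). With probes above the median Oregon R signal, the X change point moved to 21244034, with 73.9% retained proximal to it, and the shares were 80.4% in proximal 3L and 87.8% in 3LHet. YHet then had 0.051, 0.16 and -0.12 on the X, 2L and 3L array, 4 had -0.35 and -0.36 on the 2L and 3L array, XHet 0.039 on the 2L array and 2LHet -0.25 on the 3L array. These probes were centred anew on their own median, and 3L on the 2L array fell to -0.28 as well, so the zero point moved too. With loess, 2LHet had -0.49, -0.85 and -0.51 and M -2.44, -1.44 and -1.63 on the X, 2L and 3L array, YHet 1.42 and 0.86 on the 2L and 3L array, and 2R and 4 of the 2L array -0.58 and -0.027. Uextra of the 3L array was reversed (-0.048), 3LHet was retained at 78.1%, and 3 steps were found on the 3L array. Of the lists, X repeats had -1.29 on the X array, Y genes 0.64 and 0.67 on the 2L and 3L array, histone genes -2.62 on the 2L array and 3R heterochromatic genes -0.59 on the 3L array. Histone genes were reversed on the 3L array (-0.031), with His2B at -0.29 and His4 at -0.031, as was Abd-B (0.13). Subtracting the mean of the other arrays moves regions by construction, since each of those lacks an arm. On the X array it gave 1.75 for 2L, 0.33 for 2R, 0.99 for 3L, 0.31 for 3R, -0.021 for 4, 0.34 for 2RHet, 0.29 for 3LHet, 0.27 for 3RHet, 0.026 for YHet, -0.85 for M, 95% of XHet retained, 2 steps and -1.32 for proximal X genes. On the 2L array it gave 1.85 for X, 1.07 for 3L, 0.37 for 3R, -0.016 for 4, 0.31 for 3LHet, 0.31 for 3RHet, 0.81 for M (reversed), 1 step, -0.40 for Y genes and -2.09 for histone genes. On the 3L array it gave 1.41 for X, 2.36 for 2L, 0.63 for 2R, 0.025 for 4, 0.47 for 2RHet, -0.46 for YHet, 0.066 for M (reversed), 99.0% of 3LHet retained, -0.23 for Y genes and 1.41 for histone genes. With 30 to 40% G and C, the retained shares were 90%, 97.0% and 98.2% in proximal X, 2L and 3L and 100% in 3LHet, and Y genes had 0.80 on the 2L array. A fixed level of -1 kept 52.8% of proximal 2L, 83.8% of 2LHet, 68.4% of proximal 3L and 72.4% of 3LHet, and gave 1 unplaced sequence lost on the 2L array alone. That level lies next to the kept medians of -0.97 on the 2L array and -0.90 on the 3L array, so it splits kept probes. A level nearer to the lost one kept 98.7% of proximal 3L and 99.0% of 3LHet. A smallest step of 0.2 gave 2 steps on the 3L array, and 20 probes beside a step gave 1 on the 2L array. Single unplaced probes gave counts of 2624, 3995 and 6211, and genes with 1 or more probes list medians of -1.50 for proximal X genes on the X array and 0.94 for Y genes on the 2L array, since more items are counted. Apart from these and the subtraction, the cause was not tested. Scaffolds with 10 or more probes gave no value, because none of the unplaced names has that many. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out in turn. Set against the midpoint of the same setting, a count added after the data were seen, 5 of the 5 histone genes lay below it on the 2L array with loess and in the value table, and 2 with normexp. The median Cy5 signal of lost probes was 16.2, 7.72 and 26.6 times that of the negative controls, and whether signal limited the depth of a loss on the X and 2L array was not tested.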

Other observations

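All tests in this part were chosen after the results were seen, and so were the genes named. On the X array, the genes CG40813, CG41562, CG41038, CG40794, CG41545 and CG41580, which the files place on the unordered scaffolds U and Uextra, had single probes as low as the lost X euchromatin. Their ratios were -4.35 and -3.84 for CG40813, -3.56 and -3.79 for CG41562, -3.94 for CG41038, -3.73 for CG40794, -3.72 for CG41545 and -3.92 for CG41580. On the 2L array all of these lay between 0.47 and 1.02. Their log2 Cy3 signals in Oregon R ran from 11.8 to 14.2. A further 3 probes on 2L, 2 in CG10039 (-2.47 and -3.83) and 1 in cype (-3.52), were also low on the X array alone. Stellate was low not only on the X array but also on the 3L array (-1.40, 3 probes from -1.51 to -0.83), where X itself had a median of 0.07.

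The genes of the Y parted on the 2L array. The translocation behind this array also has a breakpoint on the Y, and whether the genes parted at it was not tested. The genes kl-3 (1.18), kl-2 (0.95) and ORY (0.94) lay above the median of the 2L array, and Pp1-Y1 at 4.57, while ARY and Ppr-Y, at -2.39 and -4.79, lay below the midpoint of -2.17. On the X array the same 6 genes lay at 0.84, 0.84, 0.88, 3.08, 0.89 and 0.89. Each of them had fewer than 3 usable probes. Pp1-Y1 stood far above the others on both arrays, which was not explained, and its value is not read as a number of copies.

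The tip of X was kept on the X array up to a point between ac and sc. If the tip is kept in as many copies as proximal X, both should differ by 0 once probe effects are removed with another array. With the 3L array the difference was -0.042 (95% of resamples -0.15 to 0.067), but with the 2L array it was 0.43 (0.19 to 0.56). Proximal X itself had a median of 0.70 on the 2L array and 0.04 on the 3L array, and the tip 0.16 and -0.14. The result thus depends on the array used as reference, so this test cannot decide the number of copies of the tip, which stays open.

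The first 30 probes of 3R, up to the cuticle gene TwdlV at 81113 in band 82A1, had a median of 0.59 on the 2L array. They lie at the proximal end of the arm. The rest of 3R, from the odorant receptor gene Or82a at 84046, had -0.07. Set against the X array at the same probes, the first 30 probes were higher than the rest by 0.58 (95% of resamples 0.52 to 0.67). A change from 2 to 3 copies would give 0.58 (log2 of 3 over 2), so an extra copy of this proximal part is a candidate explanation.

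Of the unplaced probes, 1693 had names starting with V. Those no brighter than arm probes had a median of -1.01 on the 2L array, -0.14 on the X array and -0.06 on the 3L array. A candidate explanation is that they lie in kept parts of chromosome 2, and among probes with 30 to 40% G and C their median on the 2L array differed from that of 2R by 0.0089 (95% of resamples -0.024 to 0.051). They might also come from another sequence that is reduced in these embryos, which was not tested.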
